A study of Mus musculus with 4 samples.

How the data were processed

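RNA from the lateral habenula of C57BL/6 mice was measured in 4 libraries, 2 from group-housed and 2 from socially isolated animals. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a stranded poly(A) kit (Illumina TruSeq Stranded mRNA LT). The submitters' processing notes name CASAVA, TopHat2 2.1.1, HTSeq and edgeR and the genome build GRCm38, without saying which step each served. The annotation release, the strand setting of the counting and the read length are not given in the sources used here. The labels do not say whether each library came from a separate animal or from a pool, so p-values measure only the spread between these samples, which may be technical.

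The authors deposited a matrix of raw read counts per Ensembl gene for the 4 libraries, and these counts were used for every test. They also deposited a normalised signal per gene for each library, which was each count of the matrix multiplied by a constant of that library (0.0499 and 0.0400 for the group-housed and 0.0393 and 0.0387 for the isolated replicates). The deposited signal summed to between 1006170 and 1042170 per library, so it is close to, but not, plain CPM. It was used only to recover those constants. Group labels were taken from the sample descriptions.

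Of 53465 gene identifiers, 53274 were matched to a symbol through a GENCODE annotation of GRCm38, which also gave coordinates and overlaps. Of the genes named, Cpne9, Mrvi1, Grin2c, Rora, Mgll, Ppp1r1b, Mt2, Vcam1, Cox4i1, mt-Nd5, mt-Nd6, Reln, Nwd2, Zic1, Neurod1, Tspan2, Gabra4, Gbx2, Ramp3, Shox2, Necab1 and Cfap43 overlap exons of another annotated gene, on either strand, and their counts are uncertain to that extent. Identifiers without a symbol held 0.0679 to 0.0887% of the counts. A total of 7 symbols were shared by more than 1 tested identifier. No count was observed in any library for 24231 identifiers, and 17528 passed the default low-count filter of edgeR (filterByExpr).

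Total counts ranged from 20897605 to 26428152 per library. Intervals and floors based on counts cover counting error only. TMM factors were 0.983 and 1.003 for the group-housed and 0.994 and 1.020 for the isolated replicates, and the top 10 genes held 2.85 to 3.30% of a library's counts. CPM values were computed from these effective library sizes. Isolated and group-housed libraries were compared with edgeR 4.0.16 in R 4.3.3 by a 2-sided quasi-likelihood test (glmQLFit and glmQLFTest) with no covariate and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. The common biological coefficient of variation was 7.20%, the prior degrees of freedom were 6.55, and the residual degrees of freedom were 2. Standard errors are the log2 fold change divided by the square root of the F statistic. Fold changes are isolated against group-housed.

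A total of 35 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 35 lists. Of these, 2 lists passed as higher and 15 as lower. With an estimated correlation between genes 0 lists passed (smallest adjusted p = 0.769), and with fry 0 passed in either the directional form (smallest adjusted p = 0.254) or the mixed form (0.0586). An adjusted p of a gene is from the edgeR test and that of a list from camera, unless stated otherwise. Fits without 1 library kept the preset correlation of 0.01. Over all 4 libraries the estimated correlation was 0.764 for mitochondrially encoded mRNAs, 0.730 for oligodendrocyte and 0.211 for medial habenula markers. A list call that held in such fits therefore does not cover the correlation between genes. Counts adjusted over the list alone apply Benjamini-Hochberg to the edgeR p-values of that list's members.

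The lists cover immediate early and activity-regulated genes, AMPA receptors, NMDA, kainate and delta receptors, metabotropic glutamate and endocannabinoid signalling, postsynaptic scaffolds, presynaptic release, GABA and glycine synapses, excitability channels, monoamine genes, neuropeptides, glucocorticoid-responsive genes, clock genes, inflammatory genes, interferon-stimulated genes, heat shock genes, the unfolded protein response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins and extracellular matrix. Marker lists cover the lateral and medial habenula, thalamus, hippocampus and cortex, choroid plexus, ependyma, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, pericytes, meningeal fibroblasts, blood and neurons in general. The groups, tests, thresholds, gene lists, the rule for named genes and the listed alternatives were chosen before the data were examined.

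Genes were named by rule. Up to 12 passing genes per direction were named, by size of change, where both isolated libraries lay on the same side of both group-housed ones. If fewer than 5 passed in a direction, the 5 genes with the smallest p in that direction were given as values, without predicted genes, pseudogenes and Y-linked genes. Of each list up to 4 members with the smallest p were eligible, with the most abundant member of each marker list, and a few sex-linked and regional genes were read per library. Not every gene the rule allows is reported here.

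The procedure was tested on simulated data of the same 17528 genes and 2 libraries per group, with 200 genes changed by these folds. The changed genes were drawn from those with a mean above 5 CPM, so recovery at lower expression was not tested. A further list of 12 genes was shifted by a log2 of 0.4. The procedure recovered 59 of 67 genes changed by 1.5-fold (88.1%), 66 of 67 changed by 2-fold (98.5%) and 66 of 66 changed by 4-fold (100%). Of its 209 calls, which include calls in the shifted list, 10 (4.78%) were false. The simulation gave every gene the trended dispersion of the data, without spread specific to a gene, so the recovery is an upper estimate. Its genes were drawn independently, so it does not test how often camera calls lists of correlated genes.

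Alternatives were other scalings (RLE, upper quartile, library size alone), no low-count filter or a mean of at least 5 CPM, leaving out each library in turn, the replicate number as a block, leaving out the genes of the marker lists, DESeq2 1.42.0, limma-voom, edgeR's exact test and robust quasi-likelihood, an adjusted p threshold of 0.1 and a log2 fold change of at least 1. The scaling constants of the authors were added as an alternative after the data were seen.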

Results

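Poly(A) RNA sequencing was used to measure gene expression in the lateral habenula, a small epithalamic nucleus that relays forebrain signals to midbrain monoamine neurons. The tissue came from C57BL/6 mice that had been group-housed or socially isolated. There were 2 libraries per group, and the series asks whether acute isolation from other mice changes the state of this nucleus. The length of isolation is not given in the sources used here. The libraries held 20897605 counts (group-housed replicate 1), 25640860 (group-housed replicate 2), 26428152 (isolated replicate 1) and 25985591 (isolated replicate 2). Between 24301 and 25616 genes had at least 1 count in a library. At these depths 3 counts corresponded to 0.114 to 0.144 CPM, that is, counts scaled to a common library total. Of the 53465 gene identifiers, 17528 had enough counts to be tested.

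Transcripts of 2 genes of cholinergic signalling rose in the isolated libraries. Chrnb3 (ENSMUSG00000031492), which encodes the β3 subunit of neuronal nicotinic acetylcholine receptors, rose from 35.5 ± 2.12 to 64.1 ± 3.72 CPM (SD, n = 2 per group), a fold of 1.81. Slc5a7 (ENSMUSG00000023945), the high-affinity choline transporter that supplies acetylcholine synthesis, rose from 62.2 ± 0.886 to 97.8 ± 0.138 CPM (SD, n = 2 per group), a fold of 1.57. Both isolated libraries lay above both group-housed libraries for each gene. The log2 fold changes were 0.85 (SE 0.08) for Chrnb3 and 0.65 (SE 0.06) for Slc5a7, each with an adjusted p = 0.0227 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On GRCm38, Chrnb3 is a protein-coding gene on the plus strand of chromosome 8 from 27368711 to 27399730, and Slc5a7 is on the minus strand of chromosome 17 from 54273590 to 54299034. No annotated exon of another gene overlapped those of either gene. Both genes stand in the list of markers of the neighbouring medial habenula, which had a median log2 fold change of 0.42. A larger share of medial habenula tissue and a change within its cells cannot be told apart here. The calls were lost without group-housed replicate 1 (edgeR adjusted p = 0.0754 for Chrnb3 and 0.137 for Slc5a7) and without group-housed replicate 2 (0.156 and 0.226).

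No gene passed as lower in this test. At an unadjusted p below 0.05 in the edgeR quasi-likelihood test, 496 genes were higher and 397 lower, 893 in all beside 876.4 that chance would give. Limma-voom called the same 2 genes, DESeq2 called 41 genes higher and 10 lower, and edgeR's exact test called 67 higher and 15 lower. Without isolated replicate 1 the quasi-likelihood test called more genes each way, among those higher the motile cilia genes Foxj1 and Dnah5. Without group-housed replicate 1 it called only Ttr, as lower, and without group-housed replicate 2 only Ttr, as higher. Across the 17528 genes, both isolated libraries lay above both group-housed libraries for 3052 (17.4%) and below them for 2850 (16.3%), where chance gives 16.7% each way.

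The genes with the next smallest p-values did not pass. Nptx1, a secreted pentraxin that clusters AMPA receptors, measured 107 ± 2.82 CPM in group-housed and 152 ± 7.62 in isolated libraries (SD, n = 2; log2 fold change 0.51). Kcnip1, a calcium-binding partner of Kv4 potassium channels, measured 69.9 ± 3.23 and 101 ± 6.13 CPM (0.53), and Cpne9 measured 126 ± 2.09 and 178 ± 7.97 CPM (0.49). The edgeR adjusted p = 0.123 held for all 3, and both DESeq2 and edgeR's exact test called these 3 genes. In the other direction, Gabrd, the δ subunit of extrasynaptic GABA-A receptors, measured 18.7 ± 3.58 CPM in group-housed and 10.5 ± 1.73 in isolated libraries (log2 fold change -0.84, edgeR adjusted p = 0.281). Grin2c, an NMDA receptor subunit, measured 34.0 ± 1.51 and 24.1 ± 2.24 CPM (-0.50, edgeR adjusted p = 0.246). Mrvi1 gave a log2 fold change of -0.81, Rtl8a of -0.35 and the nuclear receptor gene Rora of -0.49, with edgeR adjusted p-values from 0.246 to 0.328. DESeq2 called Gabrd, Rora and Rtl8a lower, and edgeR's exact test called all 5 of these genes lower. Rora is also in the list of thalamus markers, which had a median log2 fold change of -0.28 and lay lowest in isolated replicate 2. Cpne9, Mrvi1, Grin2c and Rora overlap an annotated antisense gene, and the strand setting of the counting is not given in the sources used here, so reads of the antisense partners may be included.

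Markers of the neighbouring medial habenula were higher as a group in the isolated libraries. Of 12 measured members, 11 were higher, and for these 11 both isolated libraries lay above both group-housed ones. The members had a median log2 fold change of 0.42 (range -0.03 to 0.85). The group passed camera with an adjusted p = 6.56e-11, and gave an adjusted p = 0.769 with an estimated correlation. Over all genes 2 members passed, Chrnb3 and Slc5a7, and 10 passed when adjusted over the list alone. With DESeq2 8 members passed over all genes, and with edgeR's exact test 8. Chat, the enzyme that synthesises acetylcholine, measured 24.6 ± 3.01 CPM in group-housed and 40.0 ± 4.24 in isolated libraries (SD, n = 2; log2 fold change 0.71, edgeR adjusted p = 0.167). Chrnb4, the β4 nicotinic subunit, measured 119 ± 7.27 and 156 ± 2.71 CPM (0.40), the neurokinin B gene Tac2 122 ± 3.28 and 165 ± 22.6 (0.43), and Nwd2, the most abundant member, 619 ± 34.4 and 796 ± 7.96 (0.36). The member with the lower mean, Wif1, a secreted Wnt inhibitor, had a log2 fold change of -0.03 and was picked out after its value was seen. Relative to each gene's mean over the libraries, the list's median log2 level was -0.13 and -0.30 in group-housed replicates 1 and 2 and 0.24 and 0.23 in isolated replicates 1 and 2. At the preset correlation the call of this list held when any of the 4 libraries was left out, with medians from 0.33 to 0.51.

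**Figure D1:**
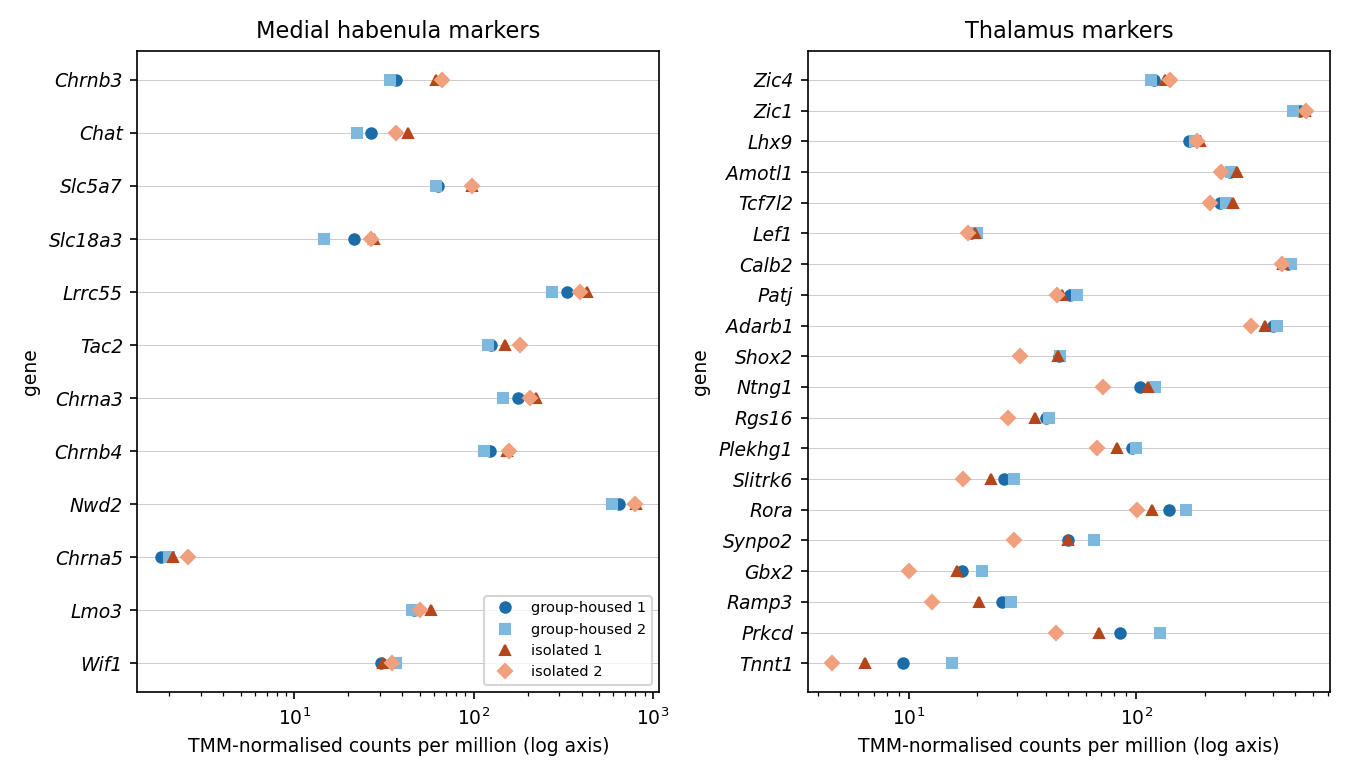
TMM-normalised expression (CPM, log axis) of each measured medial habenula marker (12 genes) and thalamus marker (20 genes) in the 4 libraries, with a marker for each library coloured by housing group. Most medial habenula markers lie higher in both isolated libraries, with a median log2 fold change of 0.42, whereas the thalamus markers lie lower, with a median of -0.28, mostly in isolated replicate 2.

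Thalamus markers were lower as a group, with 17 of 20 members lower and a median log2 fold change of -0.28 (range -1.19 to 0.22). For 12 members both isolated libraries lay below both group-housed ones, and for 3 both lay above. The camera adjusted p = 6.65e-05, with an adjusted p = 0.797 with an estimated correlation. No member passed over all genes in the quasi-likelihood test and 10 passed when adjusted over the list alone. Over all genes DESeq2 called Rora and Tnnt1 lower, and edgeR's exact test called Rora, Tnnt1, Prkcd and Plekhg1 lower. Prkcd, a protein kinase C gene of sensory thalamic relay neurons, measured 106 ± 30.1 CPM in group-housed and 56.4 ± 17.2 in isolated libraries (SD, n = 2; log2 fold change -0.91). Tnnt1 measured 12.5 ± 4.32 and 5.50 ± 1.32 CPM (-1.19), Rora 152 ± 18.5 and 109 ± 11.8 (-0.49) and Plekhg1 97.6 ± 2.56 and 74.7 ± 10.3 (-0.39). Zic1, the most abundant member, measured 509 ± 24.8 and 556 ± 3.02 CPM (0.13). The list's median level stood at 0.10 and 0.18 in the group-housed replicates, 0.02 in isolated replicate 1 and -0.34 in isolated replicate 2. Without isolated replicate 2 its call was lost (median -0.15, camera adjusted p = 0.0597), and without isolated replicate 1 its median was -0.56.

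Markers of the lateral habenula itself did not move as a group. Of 11 members 5 were higher and 6 lower, with a median log2 fold change of -0.11 and a camera adjusted p = 0.922, and fry gave the opposite direction. Over all genes 0 members passed and 2 passed when adjusted over the list alone. These were Sstr2, a somatostatin receptor, at 61.6 ± 1.45 and 72.6 ± 2.66 CPM in group-housed and isolated libraries (SD, n = 2; log2 fold change 0.24) and the transcription factor gene Pou4f1 at 133 ± 4.62 and 157 ± 7.83 CPM (0.24). Gpr151, an orphan receptor enriched in the habenula, measured 374 ± 31.5 and 426 ± 0.318 CPM (0.19). The list was lower without isolated replicate 1 (median -0.24, camera adjusted p = 0.0387), whereas its median was 0.0078 without isolated replicate 2 and -0.03 without group-housed replicate 1. Hippocampus and cortex markers gave a median of 0.17 over 12 members (7 higher, 5 lower, camera adjusted p = 0.221), which was 0.31 without group-housed replicate 2 and 0.33 with no filter on low counts (camera adjusted p = 0.0878 and 0.183). No member of that list passed over all genes and 3 passed when adjusted over the list alone, Neurod1 (0.47), Neurod2 (0.86) and Fibcd1 (0.33). Over all genes edgeR's exact test called these 3 higher, and DESeq2 did not. Pan-neuronal markers had a median of -0.04 over 15 members (camera adjusted p = 0.415, and median 0.01 without isolated replicate 2), and Rbfox3 measured 89.6 ± 1.40 and 99.9 ± 5.83 CPM.

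Markers of glial cells lay slightly lower in the isolated libraries. Both isolated libraries lay below both group-housed ones for 14 of 19 oligodendrocyte and 9 of 16 microglia markers. The same held for 9 of 15 astrocyte and 4 of 9 oligodendrocyte precursor markers. Both lay above for 0 members of these lists. All 19 oligodendrocyte and myelin markers were lower (median log2 fold change -0.23, camera adjusted p = 5.28e-07, and adjusted p = 0.797 with an estimated correlation). Mbp, myelin basic protein, measured 4425 ± 387 CPM in group-housed and 3745 ± 326 in isolated libraries (SD, n = 2; -0.24), and Tspan2 443 ± 21.2 and 359 ± 62.5 (-0.30). At the preset correlation the call held without any of the 4 libraries. The median was -0.09 without isolated replicate 1 and -0.39 without isolated replicate 2. The list's median level was 0.15 and 0.07 in the group-housed replicates, -0.28 in isolated replicate 1 and 0.03 in isolated replicate 2. The difference thus lay mainly in isolated replicate 1. All 16 microglia markers were lower (median -0.14, camera adjusted p = 1.85e-05, and adjusted p = 0.797 with an estimated correlation), among them Tmem119 at 19.1 ± 1.02 and 15.8 ± 0.363 CPM. Of 15 astrocyte markers 13 were lower (median -0.12, camera adjusted p = 0.00173, and adjusted p = 0.797 with an estimated correlation), with the glutamate transporter gene Slc1a3 at 462 ± 17.9 and 399 ± 6.76 CPM. Without group-housed replicate 1 both calls were lost (microglia median -0.03, camera adjusted p = 0.184, and astrocyte median -0.06, 0.329), and without group-housed replicate 2 the medians were -0.24 and -0.19. All 9 oligodendrocyte precursor markers were lower (median -0.10, camera adjusted p = 0.00844, and adjusted p = 0.769 with an estimated correlation), a call lost without group-housed replicate 2 (adjusted p = 0.103) or isolated replicate 1 (0.0814). In these 4 lists no member passed, either over all genes or adjusted over the list alone.

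All 12 ependymal markers were higher (median log2 fold change 0.54, camera adjusted p = 0.000926, and adjusted p = 0.797 with an estimated correlation), with the difference lying in isolated replicate 2. The list's median level was -0.26 in each group-housed library, -0.23 in isolated replicate 1 and 0.71 in isolated replicate 2, and without that library the median was 0.05 (camera adjusted p = 0.378). Without isolated replicate 1 it was 0.94. Ccdc153, a gene of motile cilia, measured 7.50 ± 0.0635 CPM in group-housed and 15.0 ± 10.3 in isolated libraries (SD, n = 2), and Dynlrb2 1.46 ± 0.140 and 3.71 ± 2.66. Choroid plexus markers varied within both groups, with medians of -0.43 and 0.46 in the group-housed and -0.31 and 0.28 in the isolated replicates (16 members, 6 higher and 10 lower, median log2 fold change -0.15, camera adjusted p = 0.944). The choroid plexus list was lower without group-housed replicate 1 (median -0.54, camera adjusted p = 4.55e-05) and higher without group-housed replicate 2 (0.38, 0.0103), and its median was 0.04 without isolated replicate 1 and 0.24 at a mean of at least 5 CPM. Ttr, the transthyretin gene, measured 3.41 and 102 CPM in the group-housed replicates and 22.1 and 26.9 in the isolated replicates. Camera adjusted p-values of the remaining marker lists also missed the threshold. They were 0.437 for 13 endothelial markers (8 higher, median 0.06), 0.911 for 12 pericyte and smooth muscle markers (7 higher, median 0.06), 0.788 for 16 meningeal fibroblast markers (7 higher, median -0.09) and 0.166 for 6 blood cell markers (0 higher, median -0.10). Without isolated replicate 1 the endothelial (median 0.12, camera adjusted p = 0.00934), pericyte (0.20, 0.0169) and meningeal (0.13, 0.0387) lists were higher. Without isolated replicate 2 the pericyte (-0.14, 0.0245), meningeal (-0.33, 0.00521) and blood cell (-0.51, 1.33e-05) lists were lower. The endothelial median was -0.09 without isolated replicate 2, the blood cell median 0.12 without isolated replicate 1 and the meningeal median 0.09 without group-housed replicate 2. No member of these 6 lists passed, either over all genes or adjusted over the list alone.

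**Figure D2:**
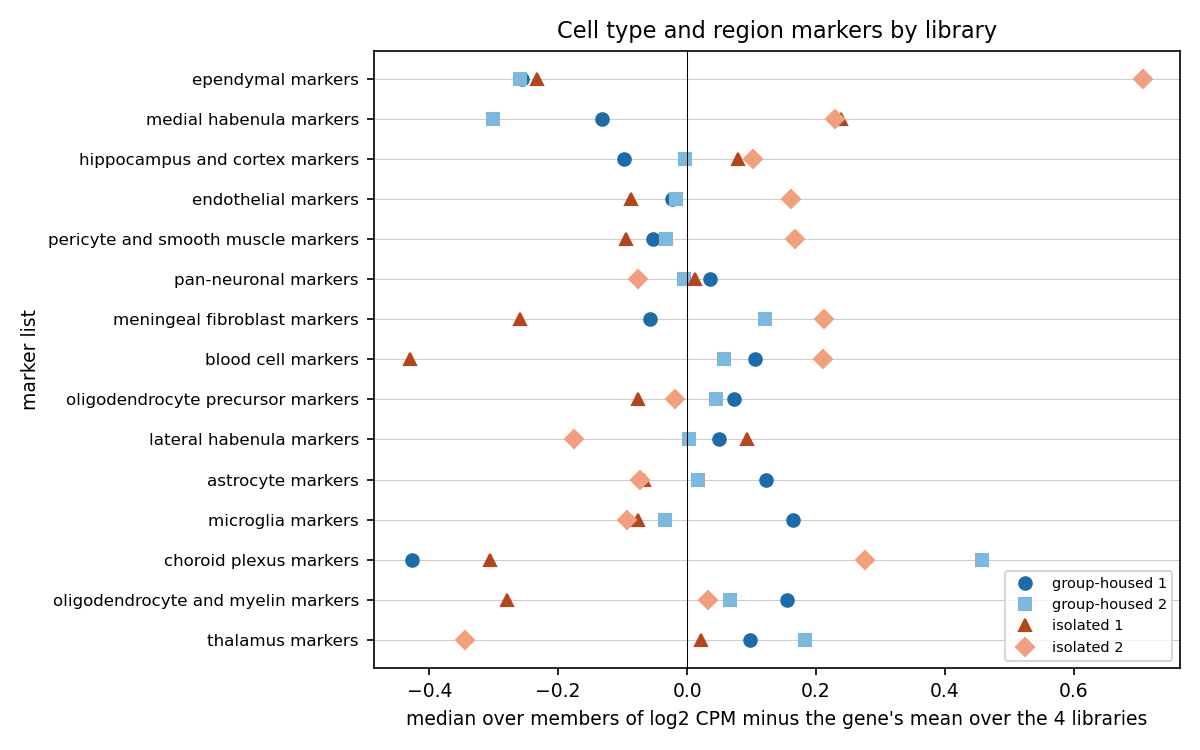
Median deviation of each marker list in each of the 4 libraries, as log2 CPM minus the gene's mean over the libraries, for 15 lists of cell type and region markers. Medial habenula markers lie at -0.13 and -0.30 in the group-housed and at 0.24 and 0.23 in the isolated libraries, while the ependymal list stands apart at 0.71 in isolated replicate 2 only.

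Genes of synaptic transmission went both ways. Of 31 postsynaptic scaffold, CaMKII and phosphatase genes, 23 were lower (median log2 fold change -0.05, camera adjusted p = 0.0280, and adjusted p = 0.982 with an estimated correlation). No member passed over all genes in the quasi-likelihood test, whereas DESeq2 called Camk2a, and edgeR's exact test Camk2a, Nrgn and Ppp1r1b. When adjusted over the list alone 3 passed. These were Camk2a, the α subunit of CaMKII, at 314 ± 13.5 CPM in group-housed and 238 ± 35.7 in isolated libraries (SD, n = 2; -0.40), Nrgn, the calmodulin-binding neurogranin, at 61.9 ± 3.25 and 79.3 ± 2.25 (0.36), and Ppp1r1b, the phosphatase inhibitor DARPP-32 gene, at 40.3 ± 3.15 and 52.4 ± 3.48 (0.38). Of 30 GABA and glycine synapse genes, 19 were lower (median -0.07, camera adjusted p = 0.0189, and adjusted p = 0.982 with an estimated correlation), with 0 passing over all genes and 1, Gabrd, adjusted over the list alone. Of 21 metabotropic glutamate and endocannabinoid genes, 15 were lower (median -0.13, camera adjusted p = 0.0133, and adjusted p = 0.797 with an estimated correlation), and none passed in either adjustment. Mgll, which degrades the endocannabinoid 2-arachidonoylglycerol, measured 146 ± 6.36 and 126 ± 4.12 CPM (-0.21). Of the 4 omissions of a library, these 3 calls held only in that of isolated replicate 1 (medians -0.10, -0.21 and -0.17). The camera adjusted p-values of the postsynaptic, GABA and metabotropic lists were 0.107, 0.110 and 0.0661 without group-housed replicate 1, 0.167, 0.0704 and 0.0878 without group-housed replicate 2, and 0.847, 0.152 and 0.409 without isolated replicate 2, where the medians were -0.02, 0.04 and -0.04. The postsynaptic call was also lost with no filter on low counts (adjusted p = 0.0660). The thalamus markers lay at -0.34 in that last library.

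AMPA receptor subunits and their auxiliary proteins showed no common direction. Of 25 genes 10 were higher and 15 lower, with log2 fold changes from -0.25 to 0.28, a median of -0.04 and a camera adjusted p = 0.761, and fry gave the opposite direction. Over all genes 0 passed and 1 passed when adjusted over the list alone, Grip2, a scaffold that binds AMPA receptor tails, at 73.5 ± 0.762 CPM in group-housed and 89.3 ± 2.17 in isolated libraries (SD, n = 2; 0.28). Of 16 NMDA, kainate and delta receptor genes 10 were lower (median -0.05, camera adjusted p = 0.394, and median 0.05 without isolated replicate 2), with 0 passing over all genes and 1, Grin2c, adjusted over the list alone. Of 36 presynaptic release genes 21 were lower (median -0.02, mean 0.008, camera adjusted p = 0.944). That list was higher without isolated replicate 2 (median 0.07, camera adjusted p = 0.00653) and lower without isolated replicate 1 (-0.11, 0.00572). Among its members, Slc17a7, the vesicular glutamate transporter VGLUT1 gene, measured 189 ± 8.93 and 233 ± 26.5 CPM (0.30). Of 34 excitability channel genes 18 were higher (median 0.0027, camera adjusted p = 0.876), a sign that turned under RLE size factors (-0.0004). Cacna1e, an R-type calcium channel subunit, measured 507 ± 25.5 and 628 ± 9.84 CPM (0.31), and Kcnq3, an M-current subunit, had a log2 fold change of -0.35. Without isolated replicate 1 the AMPA (median -0.09, camera adjusted p = 0.0169), NMDA (-0.14, 0.00922) and channel (-0.07, 0.0437) lists were lower, and without isolated replicate 2 the channel list was higher (0.06, 0.0427) and the AMPA median was 0.03. In the presynaptic and channel lists no member passed in either adjustment of the quasi-likelihood test, whereas DESeq2 and edgeR's exact test called Cacna1e higher.

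Monoamine and neuropeptide genes likewise gave no group call. Of 28 monoamine receptor, transporter and enzyme genes 13 were higher and 15 lower (median log2 fold change -0.02, camera adjusted p = 0.761). Th, the rate-limiting enzyme of catecholamine synthesis, measured 7.38 ± 1.61 CPM in group-housed and 11.9 ± 1.11 in isolated libraries (SD, n = 2; 0.68), and the dopamine D2 receptor gene Drd2 11.5 ± 0.195 and 8.42 ± 1.61 (-0.45). Of 44 neuropeptide and neuropeptide receptor genes 20 were higher and 24 lower (median -0.04, camera adjusted p = 0.772). Cck measured 40.9 ± 2.05 and 31.9 ± 0.667 CPM (-0.36), Tacr1, the substance P receptor, 65.3 ± 5.69 and 80.8 ± 7.22 (0.31), and somatostatin, Sst, 12.7 ± 2.88 and 18.9 ± 2.86 (0.57). Both lists were lower without isolated replicate 1 (medians -0.11 and -0.12, camera adjusted p = 0.0437 and 0.0190), and their medians were 0.06 and 0.04 without isolated replicate 2. The monoamine median was 0.02 at a mean of at least 5 CPM and 0.02 without group-housed replicate 1. No member of either list passed, over all genes or adjusted over the list alone.

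**Figure D3:**
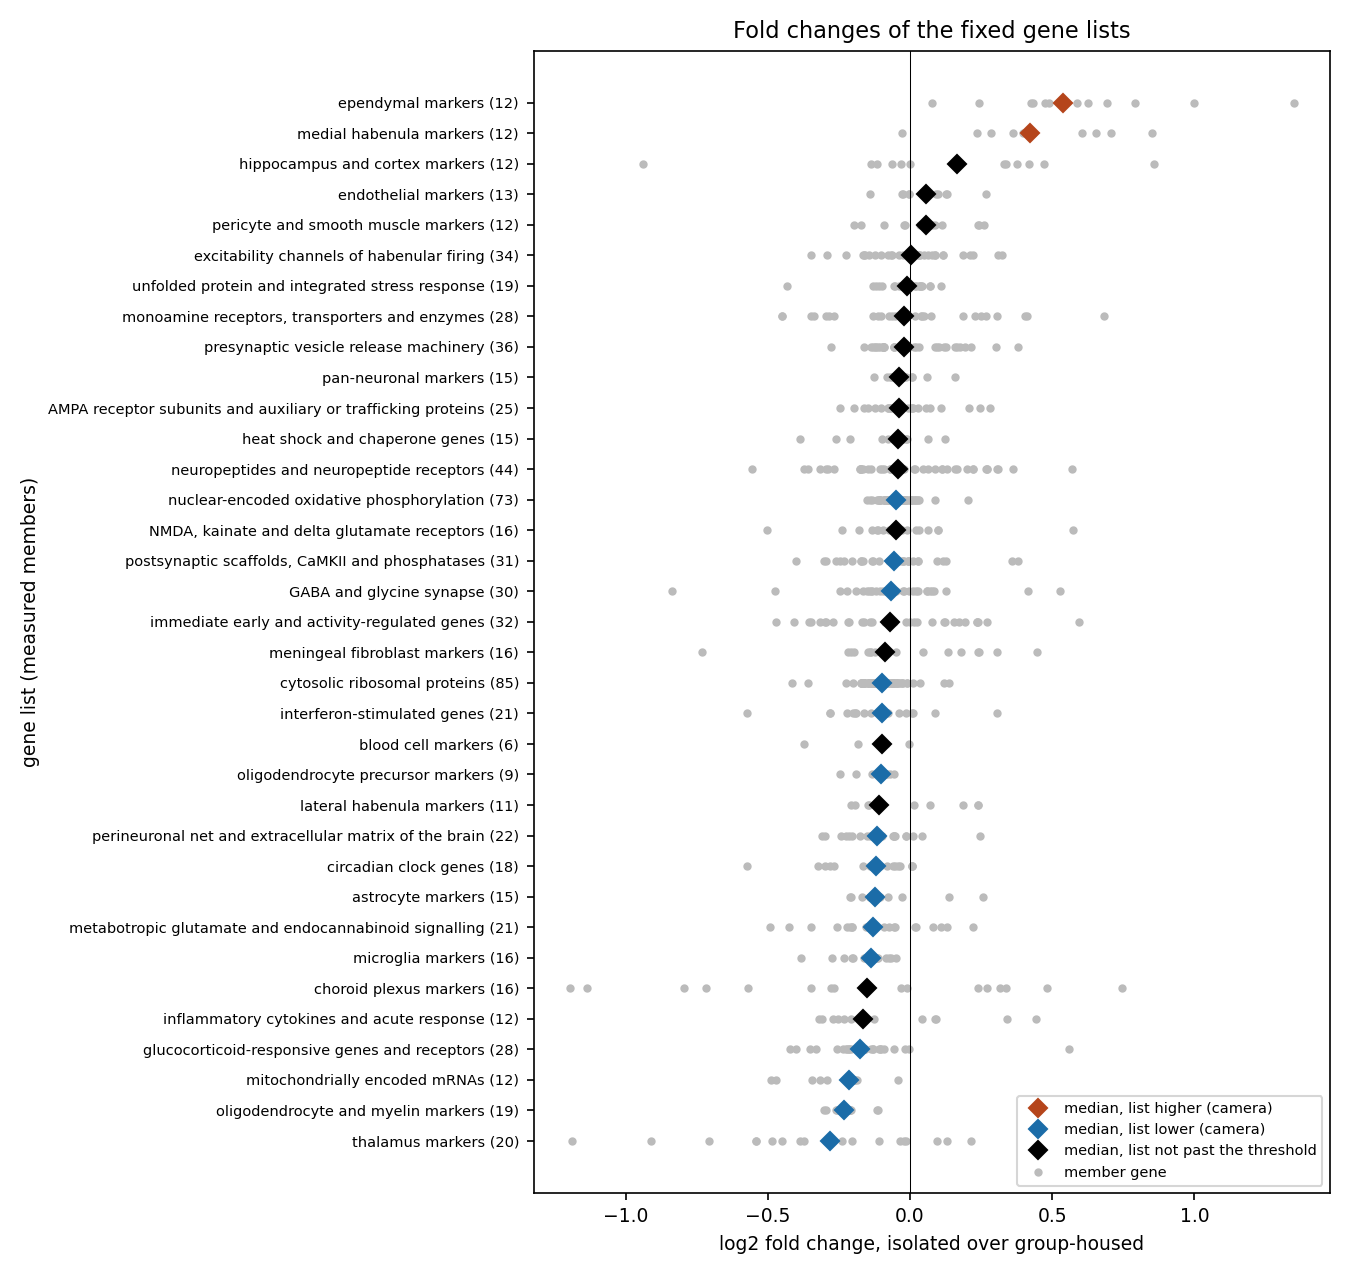
Log2 fold change, isolated against group-housed, of every measured member (dots) of the 35 gene lists, with each list's median as a diamond, coloured by whether the list passed camera as higher (2 lists), passed as lower (15 lists) or did not pass. With an estimated correlation between genes 0 lists passed camera (smallest adjusted p = 0.769). The medial habenula list has a median of 0.42 and the ependymal list of 0.54, while the medians of most synaptic lists lie near 0.

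Activity-regulated genes did not form a group either. Of 32 immediate early and activity-regulated genes 14 were higher and 18 lower (median log2 fold change -0.07, camera adjusted p = 0.437), with no member passing in either adjustment. The list was lower without group-housed replicate 2 (median -0.12, camera adjusted p = 0.00823), whereas its median was 0.12 without group-housed replicate 1 and 0.07 without isolated replicate 1. Fosb, a transcription factor induced by repeated stimulation, measured 6.89 ± 0.941 CPM in group-housed and 4.95 ± 1.02 in isolated libraries (SD, n = 2; -0.47), and the secreted pentraxin Nptx2 157 ± 6.61 and 185 ± 0.472 (0.24).

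Glucocorticoid-responsive genes were lower as a group, 27 of 28 (median log2 fold change -0.17, camera adjusted p = 0.000115, and adjusted p = 0.769 with an estimated correlation). The exception was Map3k6, a stress-activated kinase, at 30.0 ± 1.45 CPM in group-housed and 44.3 ± 1.10 in isolated libraries (SD, n = 2; 0.56). It was also the 1 member that passed adjusted over the list alone, and 0 passed over all genes. DESeq2 and edgeR's exact test both called Map3k6 higher over all genes. The oligodendrocyte (-0.23), microglia (-0.14) and astrocyte (-0.12) markers were also lower, each with an adjusted p = 0.797 with an estimated correlation. By library, the glucocorticoid list's median level was highest in group-housed replicate 2 (0.17), and those of the 3 glial lists in group-housed replicate 1 (0.15, 0.16 and 0.12). The glucocorticoid receptor gene Nr3c1 measured 91.5 ± 3.87 and 80.5 ± 0.215 CPM (-0.18), and metallothionein Mt2 99.5 ± 8.41 and 83.3 ± 5.24 (-0.26). Of 18 circadian clock genes 15 were lower (median -0.12, camera adjusted p = 0.00908, and adjusted p = 0.769 with an estimated correlation), with Npas2 at 11.9 ± 1.95 and 7.99 ± 1.63 CPM (-0.57). Without group-housed replicate 2 both calls were lost (glucocorticoid median -0.12, camera adjusted p = 0.204, and clock -4.8e-05, 0.246), and the clock call was also lost without isolated replicate 1 (-0.04, 0.0733). The clock median was -0.18 without group-housed replicate 1. Of 21 interferon-stimulated genes 17 were lower (median -0.10, camera adjusted p = 0.0108, and adjusted p = 0.797 with an estimated correlation), with Ifit3 at 7.94 ± 1.38 and 5.31 ± 0.515 CPM (-0.57). That call was lost without group-housed replicate 1 (median -0.04, adjusted p = 0.811), without isolated replicate 1 (0.172) or with no filter on low counts (0.0556), and its median was -0.25 without group-housed replicate 2. Of 12 inflammatory genes 7 were lower (median -0.17, camera adjusted p = 0.283, and medians from -0.25 without isolated replicate 2 to 0.08 without isolated replicate 1), with the adhesion molecule gene Vcam1 at a log2 fold change of -0.21. In the clock, interferon and inflammatory lists no member passed in either adjustment.

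Transcripts of the ribosome and of energy metabolism lay lower by small amounts. Both isolated libraries lay below both group-housed ones for 39 of 85 ribosomal protein genes and above for 2. For mitochondrially encoded mRNAs these numbers were 10 of 12 and 0. Of 85 cytosolic ribosomal protein genes 81 were lower (median log2 fold change -0.10, camera adjusted p = 2.49e-09, and adjusted p = 0.797 with an estimated correlation), with Rps14 at 126 ± 14.0 CPM in group-housed and 108 ± 5.74 in isolated libraries (SD, n = 2). Without group-housed replicate 1 the median was -0.04 and the call was lost (camera adjusted p = 0.0963), and without group-housed replicate 2 the median was -0.17. Ribosomal protein genes have many processed pseudogenes, so their counts may be split between copies. All 12 mitochondrially encoded mRNAs were lower (median -0.22, camera adjusted p = 1.18e-06, and adjusted p = 0.797 with an estimated correlation). At the preset correlation their call held without any of the 4 libraries. The median ran from -0.34 without group-housed replicate 2 to -0.13 without group-housed replicate 1. The complex I subunit mt-Nd5 measured 2879 ± 187 and 2472 ± 37.9 CPM (-0.22), and mt-Nd6, which lies antisense to it, 44.8 ± 5.49 and 31.9 ± 6.55 (-0.49). Of 73 nuclear-encoded oxidative phosphorylation genes 61 were lower (median -0.05, camera adjusted p = 0.00304, and adjusted p = 0.982 with an estimated correlation), with Cox4i1 at 341 ± 25.2 and 307 ± 4.90 CPM. Of 22 perineuronal net and extracellular matrix genes 19 were lower (median -0.12, camera adjusted p = 0.00550, and adjusted p = 0.769 with an estimated correlation), while Reln, the secreted guidance protein reelin, measured 113 ± 2.35 and 135 ± 3.86 CPM (0.25). The last 2 calls were lost without group-housed replicate 1 (adjusted p = 0.942 and 0.0661) or isolated replicate 2 (0.0875 and 0.102). The oxidative phosphorylation median was -0.0041 without group-housed replicate 1 and -0.10 without group-housed replicate 2, and the matrix median was -0.08 without group-housed replicate 1. Heat shock and chaperone genes (15, of which 13 lower, median -0.04) and unfolded protein and integrated stress response genes (19, of which 10 lower, median -0.01) did not pass (camera adjusted p = 0.394 and 0.788). The sign of the unfolded protein list turned when library size alone was used (0.0079), and the list was lower without isolated replicate 1 (-0.24, camera adjusted p = 0.0190). Its median was 0.13 without group-housed replicate 1 and 0.13 without isolated replicate 2. The heat shock list was higher without group-housed replicate 1 (0.09, camera adjusted p = 0.00322) and lower without group-housed replicate 2 (-0.23, 6.07e-07). No member of these 6 lists passed in either adjustment.

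The libraries of a group were about as far apart as those of different groups. Across genes, Pearson's r of log2 CPM was 0.994 between the group-housed libraries, 0.993 between the isolated libraries and 0.992 to 0.995 between groups, where genes are not independent replicates. The median absolute log2 difference was 0.108 and 0.124 within the groups and 0.105 to 0.135 between them. Chi-square per degree of freedom ranged from 5.05 to 8.56 over the 6 pairs, so no pair differed by as little as counting noise. In every library the Y-linked gene Ddx3y had 1738 to 2379 counts and Xist 1 to 3 counts, as in male tissue. Slc17a6, the vesicular glutamate transporter of habenular and thalamic neurons, measured 434 and 439 CPM in the group-housed and 439 and 381 in the isolated replicates. Tcf7l2, a transcription factor of the thalamus and habenula, measured 234 and 249 CPM in the group-housed and 266 and 210 in the isolated replicates.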

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

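Of the results here, the scaling constants of the authors were tried only after the data were seen. The calls of Chrnb3 and Slc5a7 kept their direction and side of the threshold under RLE, upper quartile, library size alone, a mean of at least 5 CPM, limma-voom, robust quasi-likelihood, the authors' scaling constants and a threshold of 0.1, each with 2 genes higher and 0 lower. Both genes were also among the 15 genes higher and 0 lower with no filter on low counts (29234 genes tested), the 41 higher and 10 lower with DESeq2, and the 67 higher and 15 lower with edgeR's exact test. The cause of the larger counts was not tested. With a log2 fold change of at least 1 required, 0 genes were higher. With the genes of the marker lists left out, which removes both called genes, 0 were higher or lower (smallest edgeR adjusted p = 0.114, 884 genes at an unadjusted p below 0.05). Leaving out each library in turn gave 0 to 151 genes higher and 0 to 70 lower, with 151 and 70 without isolated replicate 1, where the lone isolated library was assumed to vary like the group-housed ones.

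The replicate numbers are shared by the groups without a stated link. Same-numbered libraries deviated together weakly (r = 0.141 across genes, over 2 pairs), which does not establish pairing. With the replicate number as a block, 52 genes were higher and 12 lower, and the lists gave 2 higher and 15 lower.

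For the lists, 2 higher and 15 lower became 0 and 0 with an estimated correlation and 0 and 0 with fry, 2 and 13 with no filter on low counts, and 3 to 5 higher and 7 to 20 lower when each library was left out. Directions turned in some omissions, where the cause was not tested. The medians (log2) ranged from -0.10 to -0.019 for postsynaptic scaffolds (camera's direction alone turned), -0.11 to 0.066 for presynaptic release, -0.21 to 0.041 for GABA and glycine synapses, -0.074 to 0.064 for excitability channels, -0.23 to 0.087 for heat shock genes, -0.10 to -0.0041 for nuclear-encoded oxidative phosphorylation (camera's direction alone turned), -0.62 to 0.38 for choroid plexus, -0.14 to 0.20 for pericytes, -0.33 to 0.13 for meningeal fibroblasts, and -2.06 to 2.83 for the log2 fold change of Ttr. Among lists without a call over all 4 libraries, other medians also turned, with ranges of -0.24 to 0.0078 for lateral habenula markers, -0.12 to 0.12 for immediate early genes, -0.24 to 0.13 for the unfolded protein response, -0.25 to 0.08 for inflammatory genes, -0.14 to 0.05 for NMDA, -0.09 to 0.03 for AMPA, -0.11 to 0.06 for monoamine genes, -0.12 to 0.04 for neuropeptide genes, -0.09 to 0.12 for endothelial, -0.51 to 0.12 for blood cell and -0.10 to 0.01 for pan-neuronal markers. In all, 18 lists had a median on the other side of 0 under some alternative. Over lists and alternatives, 344 results kept camera's direction and side of the threshold (8 of them with a median that turned), 58 lost and 15 gained a call, 27 moved and 9 reversed. For named genes these numbers were 1998, 4, 69, 31 and 1. No scaling moved the median of all genes by more than 0.023 (log2). The per-library files hold the counts of the matrix times a constant, so the alternative of using them gave no separate value. Genes below about 0.114 to 0.144 CPM could not be distinguished from 0 at these depths.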

Other observations

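Of the tests in this part, the one on medial habenula genes outside the cholinergic set, the use of the planned omission of group-housed replicate 1 as a test of library size, and the genes named in the next paragraphs were chosen after their results were seen. Among the 41 genes that DESeq2 called higher, some outside the lists were higher in both isolated libraries without passing the quasi-likelihood test, and 4 of these are given as examples. Robo3, a receptor for commissural axon guidance, measured 122 ± 4.54 CPM in group-housed and 177 ± 13.1 in isolated libraries (SD, n = 2; log2 fold change 0.54). The synaptotagmin gene Syt9 measured 267 ± 17.0 and 367 ± 10.5 CPM (0.46), Cadps2, a factor of dense-core vesicle release, 138 ± 0.498 and 188 ± 12.5 (0.45), and the phosphodiesterase gene Pde1a 69.8 ± 2.72 and 95.5 ± 3.61 (0.45). The edgeR adjusted p-values of these 4 genes were 0.123 to 0.167. Among genes that DESeq2 called lower, Necab1, a neuronal calcium-binding protein gene, measured 155 ± 11.5 and 107 ± 21.3 CPM (-0.54, edgeR adjusted p = 0.409).

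The ependymal marker Foxj1, a regulator of motile ciliogenesis, measured 25.9 and 22.4 CPM in the group-housed replicates, 22.9 in isolated replicate 1 and 44.8 in isolated replicate 2. Cfap43 measured 6.48, 7.16, 8.53 and 17.4 CPM in the same order, and the axonemal dynein gene Dnah5 12.1, 10.8, 13.8 and 21.8. Foxj1, Cfap43, Dnah5 and other Cfap, Dnah and Ccdc genes were among those called higher without isolated replicate 1. Isolated replicate 2, where the ependymal list stood apart, was then the only isolated library. The 70 genes called lower without isolated replicate 1 included the thalamus markers Prkcd, Tnnt1, Ramp3, Gbx2 and Shox2 beside the synaptic genes Camk2a, Gabrd, Gabra4 and Grin2c.

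Medial habenula markers were higher in both isolated libraries, and the only 2 genes called belong to them. Within the list the rise was not confined to the cholinergic genes, as the other 5 members had a median log2 fold change of 0.36 (range -0.03 to 0.43). The list was singled out by its difference and this split was chosen afterwards. The value therefore carries little weight against a change of the cholinergic genes alone. The median was 0.51 without the smaller library, group-housed replicate 1. That omission could not test library size, as the list already stood lower in group-housed replicate 2 (-0.30) than in replicate 1 (-0.13). All libraries were also thinned to 20897605 counts, which was not among the listed alternatives. At equal depth 2 genes were higher and 0 lower, and the list's median was 0.42. Random thinning keeps each gene's expected share of its library. The median could therefore hardly move, and it gives no evidence on library size. A larger share of medial habenula tissue in the isolated dissections may account for the pattern, and a second list of 10 medial habenula genes had a median of 0.13, between the values set beforehand for and against it. Of that list 7 were higher, such as Gng8 (0.24) and Kcng4 (0.30), Spon1 (-0.12) was lower in both isolated libraries, and 2 also stand in other lists. Tissue share and a change within medial habenula cells after isolation therefore cannot be told apart here, as the second list's members go both ways.

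For 12 of 20 thalamus markers both isolated libraries lay below both group-housed ones, and for 3 both lay above. The list was lower mainly in isolated replicate 2. Less thalamic tissue in that library alone could account for this, and without it the median log2 fold change was -0.15, between the values set beforehand for and against. The camera adjusted p was then 0.0597, with isolated replicate 1 as the only isolated library and assumed to vary like the group-housed ones, so an effect of isolation on thalamic transcripts stays open.

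Ribosomal protein mRNAs were lower by a median log2 fold change of -0.10. Without group-housed replicate 1 the median was -0.04 (-0.0399), inside the range set beforehand for that library alone carrying the difference. Relative to each gene's mean, the list's median level was 0.11 and -0.01 in group-housed replicates 1 and 2. In isolated replicates 1 and 2 it was -0.07 and -0.02. Isolated replicate 1 thus also stood apart, and the omission does not settle whether group-housed replicate 1 alone carried the difference. Random lists matched on exon length and expression had a mean median of -0.04 (-0.0405), and 0% of 10000 reached -0.10. Members of the ribosomal list vary together, with an estimated correlation of 0.621, so random lists understate its spread and a trend with length cannot be told apart from the group difference.

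The 4 libraries can be divided into pairs in 3 ways, too few for a share under 0.05. The housing groups gave 2 genes past the threshold and 1 of the 3 divisions, the real one, gave as many, while the highest of the others gave 1 gene. The median difference of the medial habenula list was 0.42 for the housing groups and -0.06 and -0.07 for the others. That list was singled out by its difference between the housing groups, so smaller values in the other divisions followed from the choice and carry no weight.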
